A study of Homo sapiens with 4 samples.

How the data were processed

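GATA6 ChIP-Seq and matching IgG control libraries were made from 2 human gastric carcinoma lines, AGS and HUG1N, with 1 library of each kind per line. Per the labels' protocols, AGS was cultured on plates in DMEM and HUG1N in suspension in RPMI. Fixation was with formaldehyde, libraries were prepared with an NEB kit, and the GATA6 antibody came from Cell Signaling. Growth mode and medium thus differ together with the line and cannot be separated from it.

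The submitters' processing notes name CASAVA, Bowtie, MACS 1.4 and MACS 1.4.2, and the genome build hg18. They give no order or settings for these tools, and the parameters are not given in the sources used here. Per the labels, 1 peak list was deposited per line, and each list is named for both the GATA6 and the IgG library of that line, so peaks were called per line with no replicates to pool. That each list was called against its IgG library is read from this pairing. The deposited score of each peak was taken as MACS's score, 10 times the negative log10 of the caller's p. This reading rests on the peak names and on the lowest scores of 50 in AGS and 50.01 in HUG1N. Scores depend on read depth and on the control, so they serve to rank peaks within a list. Between lists they were tested only as log2 ratios of shared pairs on 1 chromosome against the others. A limit of at least 100 was also applied to both lists, and it need not be equally strict in both. Depth is unknown, so its effect on the number and scores of peaks was not measured.

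As a check of the build, peak positions were set against the last gene end per chromosome in a gene table of GRCh38. On 7 chromosomes, 114 peaks started beyond it, so that table was not used for positions. No coordinate was converted.

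All computing was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Peaks sharing at least 1 bp counted as overlapped. Chance overlap came from 1000 circular rotations of one list along each chromosome. Shares have exact Clopper-Pearson 95% intervals. Peaks were split into 5 equal bins of their own list's score. Peaks per chromosome (23 tested, chromosome Y left out) and per 5 Mb window with at least 10 peaks in both lists together were compared by two-sided Fisher exact tests with Benjamini-Hochberg adjustment. A window was called at an adjusted p under 0.05 and a difference of at least 2-fold in share. Where a list had no peak in a window, the fold was computed against a floor of 3 peaks and is a lower bound. Clusters joined peaks with gaps of up to 10 kb and had 5 or more peaks.

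Tests, alternatives and the rule for named items were fixed before the data were examined. With no annotation of the build, that rule names the 10 peaks with the highest score per list, the 10 shared pairs with the smallest worse rank, the 5 highest peaks of each list without a partner, up to 10 called windows per direction with the largest difference first, and the 5 clusters with the most peaks per list. Ties in score go to the wider peak, then to chromosome and start. The rule did not say on which scale the difference between windows is ranked. Windows were first ranked by fold, with windows that had no peak in the other list placed first as infinite folds, and after that list was seen the ranking was changed to the difference in share of the list. In the fold ranking, 9 of the 10 windows higher in AGS had no HUG1N peak, 3 were on chromosome X, and 1 was also among the 10 ranked by share. Of the 10 windows higher in HUG1N, 5 were in both rankings. The fold ranking for AGS began with chromosome X from 25000001 to 30000000 (19 AGS peaks and 0 HUG1N peaks, at least 4.07-fold). The chromosome 13 window from 60000001 to 65000000 (25 and 1 peaks, 16.1-fold) came after the windows without a HUG1N peak. For HUG1N it began with chromosome 18 from 20000001 to 25000000. The ranking decides only which windows are named, and no call depends on it.

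Dense blocks, and every setting that leaves them out, were chosen after the data were seen. A block is a run of 100 kb windows with 5 or more peaks, allowing up to 2 successive windows below that, with 20 or more peaks in all. Leaving out the blocks of either list removed 2109 AGS and 102 HUG1N peaks. Other settings, fixed before the data were examined, were a score of at least 100, overlap of at least 50% of the shorter peak, centres within 500 bp, lists of equal size or of 5000 peaks, random moves of up to 100 kb, clusters counted once, windows of 1 and 10 Mb, and gaps of 5 and 20 kb.

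The overlap, window and chromosome steps were tested on simulated data. Of 10 windows given 4-fold more AGS peaks, 10 were recovered, with 0 others called among 608 tested. A simulated share of 10% was recovered as 9.98%. With no simulated difference, 0 windows and 0 chromosomes were called. Apart from the added windows and shared positions, simulated peaks were placed singly at random along the chromosomes, without the clustering of the real lists. These counts therefore do not give the rate of false calls in the real lists.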

Results

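Binding of GATA6, a zinc finger transcription factor of the gut endoderm, was measured by ChIP-Seq in 2 human gastric carcinoma cell lines. AGS is an adherent gastric adenocarcinoma line. The other line is named HUG1N in the sample titles and HuG-1 in the cell line field, and is called HUG1N here. Each line contributed 1 GATA6 library and 1 IgG control library, 4 libraries in all, and 1 peak list. With 1 library per group there was no replicate spread, so every test below compares 2 peak lists and not the lines as conditions. Read depth is unknown, because the peak lists hold no read counts. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only. Positions are 1-based on hg18, the build named in the submitters' processing notes.

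The AGS list held more peaks than the HUG1N list, and its highest scores were concentrated in a few regions of chromosomes 8, 10 and 11. AGS had 14756 peaks covering 5112 kb, and HUG1N had 9466 peaks covering 2625 kb. The median peak width was 201 bp in AGS and 235 bp in HUG1N. The authors' peak score, 10 times the negative log10 of the caller's p, had a median of 59.3 in AGS and 71.3 in HUG1N, and is used in these comparisons only to rank or filter peaks within a list. Scores of at least 100 were reached by 2306 AGS peaks (15.6%) and by 2869 HUG1N peaks (30.3%). Peaks wider than 1000 bp numbered 523 in AGS and 91 in HUG1N. At the stricter score HUG1N thus had the longer list, but with depth unknown this limit need not be equally strict in both lists.

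Sites present in both peak lists were counted by overlap of at least 1 bp. In AGS, 1046 of 14756 peaks (7.09%, interval 6.68 to 7.52%) overlapped a HUG1N peak. In HUG1N, 1010 of 9466 peaks (10.7%, interval 10.1 to 11.3%) overlapped an AGS peak. The remaining 13710 AGS peaks and 8456 HUG1N peaks had no partner. Rotating one list along each chromosome 1000 times gave a mean of 32.8 ± 8.56 (SD) overlapped AGS peaks and a highest count of 78. The observed number was 31.9 times that mean (one-sided permutation test by rotation, p = 0.001, the smallest that 1000 rotations can give). Rotation tests placement only and cannot tell GATA6 binding in both lines from other signal common to both libraries. Moving peaks by random distances of up to 100 kb, a background that keeps the regional density, lowered the fold to 9.17 for AGS and 13.1 for HUG1N. Among peaks with a score of at least 100 in both lists, 14.7% of AGS peaks and 11.5% of HUG1N peaks were overlapped. With the dense regions described below left out as well, a choice made after the data were seen, the AGS share was 31.5% (314 of 996 peaks) and the HUG1N share 11.1% (314 of 2830).

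Peaks with high scores were overlapped far more often than peaks with low scores in both lines. In HUG1N the overlapped share rose from 2.27% (interval 1.65 to 3.05%) in the lowest of 5 equal score bins to 30.5% (28.5 to 32.7%) in the highest. In AGS it rose from 2.10% (1.61 to 2.68%) to 19.4% (17.97 to 20.9%). The difference between the highest and the lowest bin was 28.3 percentage points in HUG1N (26.1 to 30.5) and 17.3 in AGS (15.8 to 18.8). The very top of the lists behaved differently. Of the 50 HUG1N peaks with the highest scores, 37 were overlapped (74.0%, 59.7 to 85.4%). In AGS, 101 peaks had scores of 3100 or more, 97 of them tied at 3100, and 10 of the 101 were overlapped (9.90%, 4.85 to 17.5%). With the dense regions left out, 35 of the 50 highest AGS peaks were overlapped (70.0%, 55.4 to 82.1%). That AGS list still held 9 mitochondrial peaks, with scores of up to 2325, where HUG1N had 0 peaks to overlap them.

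**Figure D1:**
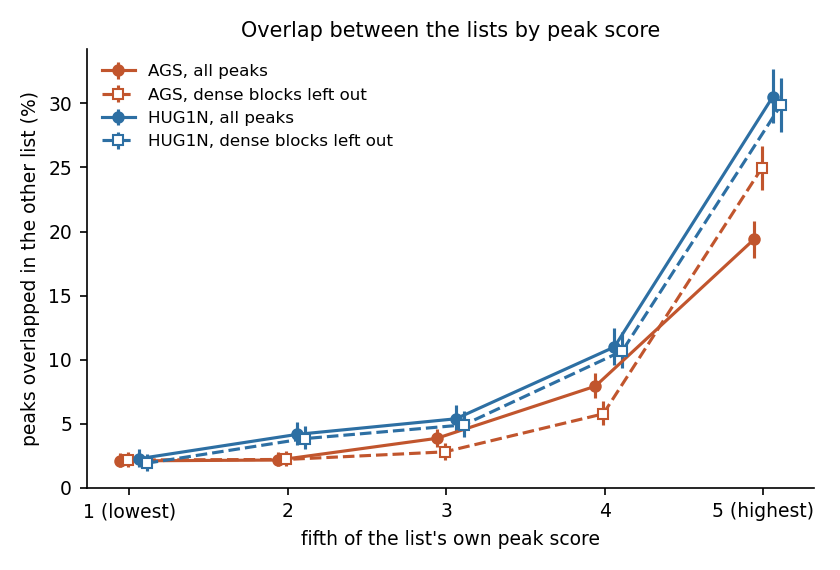
Share of peaks (%) overlapped in the other list, by bin of the list's own peak score (5 equal bins), for AGS and HUG1N, with all peaks (filled) and with dense blocks left out (open); bars are exact 95% intervals for counting error. The share rises in both lines, from 2.27% to 30.5% in HUG1N and from 2.10% to 19.4% in AGS.

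Among the shared pairs with the best worse rank, most lay in the dense regions and the others on chromosomes 1 and 6. Of the 10 best pairs, 3 were on chromosome 10, 3 on chromosome 1, 2 on chromosome 11, and 1 each on chromosomes 6 and 8. The 6 pairs on chromosomes 8, 10 and 11 lay in dense AGS blocks. AGS peaks covered 56.9 to 77.0% of the length of these blocks, so a HUG1N peak there can overlap an AGS peak by coverage alone. Outside the blocks, the pair on chromosome 1 at 237442741 to 237443308 had scores of 942.69 in AGS and 1741.54 in HUG1N. A chromosome 1 pair starting at 230884633 had scores of 731.90 and 2255.47, and a pair starting at 201054562 had 742.02 and 805.54. The chromosome 6 pair starting at 10359011 had 729.30 and 1002.73.

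The distribution of peaks over chromosomes differed between the lists. Shares per chromosome and per window are shares of a list's peaks on the 23 chromosomes tested. Chromosomes 3, 6, 18 and 20 held a larger share of the HUG1N list, and chromosomes 13, 14 and X a larger share of the AGS list. Chromosome 18 held 298 HUG1N peaks (3.15%) and 168 AGS peaks (1.14%), a 2.76-fold difference in share (two-sided Fisher exact test, adjusted p = 1.2e-26). Chromosome 3 differed 1.72-fold (exact adjusted p = 1.1e-26), chromosome 20 1.86-fold (exact adjusted p = 9.0e-15) and chromosome 6 1.59-fold (exact adjusted p = 7.8e-21) in the same direction. Chromosome X held 601 AGS peaks (4.09%) and 108 HUG1N peaks (1.14%), a 3.58-fold difference (exact adjusted p = 1.2e-43). Chromosome 14 was 2.19-fold higher in AGS (exact adjusted p = 5.9e-19) and chromosome 13 1.77-fold (exact adjusted p = 4.3e-10). Of 23 chromosomes tested, 9 had a larger share in AGS and 7 in HUG1N at an adjusted p under 0.05. These p-values treat neighbouring peaks as independent and are therefore too small.

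A score limit changed part of this picture, and much of that change ended when the dense blocks were left out as well. At a score of at least 100 in both lists, the HUG1N excess was 3.84-fold on chromosome 3, 3.00-fold on chromosome 6 and 3.74-fold on chromosome 18, and the AGS excess 4.603-fold on chromosome 10 and 2.97-fold on chromosome 11. At the same score, chromosome X held 29 AGS and 28 HUG1N peaks and the call ended (1.30-fold, exact adjusted p = 0.365). The AGS calls on chromosomes 13 and 14 ended too and their direction turned, with shares 1.31-fold (exact adjusted p = 0.288) and 1.03-fold (exact adjusted p = 0.923) higher in HUG1N. With dense blocks left out as well, on chromosome X the same 29 and 28 peaks gave a 3.00-fold difference (exact adjusted p = 0.000502). The 29 AGS peaks were then 2.97% of the AGS peaks on the tested chromosomes instead of 1.27%. Under that combined setting, chosen after the data were seen, chromosome 3 was higher in HUG1N (1.61-fold, exact adjusted p = 0.00555) and chromosome 14 in AGS (2.24-fold, exact adjusted p = 0.000502). Chromosome 18 no longer passed the test there, with 89 HUG1N and 19 AGS peaks (1.62-fold, exact adjusted p = 0.131). Chromosomes 6 (1.30-fold higher in HUG1N), 20 (1.18-fold higher in HUG1N) and 13 (1.76-fold higher in AGS, exact adjusted p = 0.0563) did not pass either. The shares of chromosomes 10, 11 and 12 were 1.54-, 1.32- and 1.41-fold higher in AGS with all peaks and turned to HUG1N without the dense blocks.

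**Figure D2:**
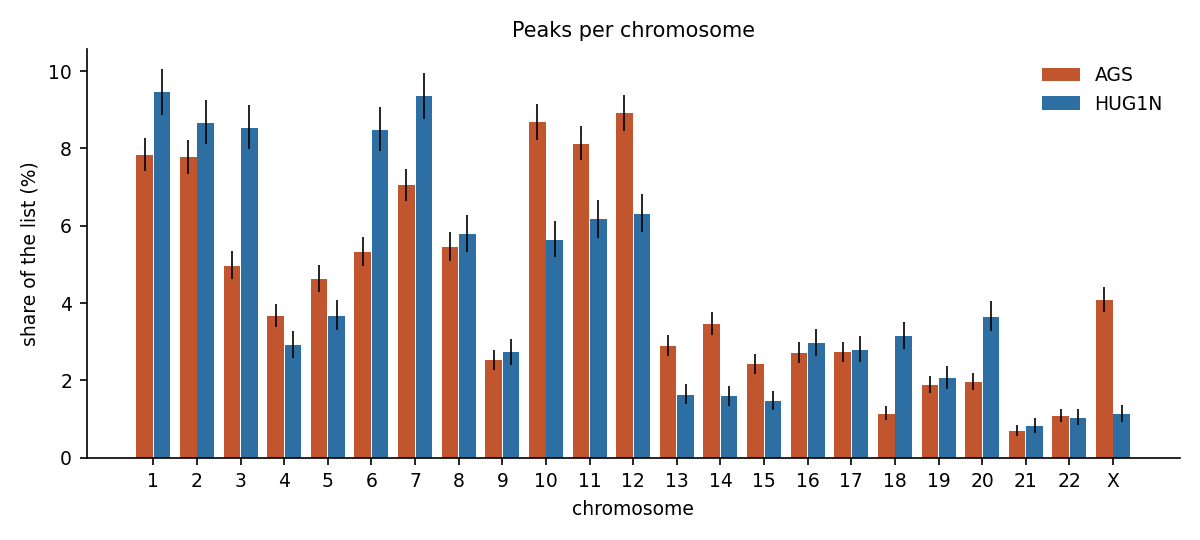
Peaks per chromosome as a share (%) of each list for AGS and HUG1N, with exact 95% intervals for counting error as bars. Chromosome X stands out for AGS (4.09% against 1.14%) and chromosome 18 for HUG1N (3.15% against 1.14%).

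Windows of 5 Mb located these differences. The windows with the largest excess of AGS peaks lay on chromosomes 10, 11, 12 and 8, and those with the largest excess of HUG1N peaks on chromosomes 3, 18 and 6. Chromosome 10 from 120000001 to 125000000 held 713 AGS and 30 HUG1N peaks (15.3-fold in share, exact adjusted p = 5.3e-113). Chromosome 11 from 35000001 to 40000000 held 516 and 50 (6.64-fold), chromosome 12 from 20000001 to 25000000 held 368 and 25 (9.46-fold), and chromosome 8 from 125000001 to 130000000 held 191 and 36 (3.41-fold). In the other direction, chromosome 3 from 170000001 to 175000000 held 90 HUG1N and 54 AGS peaks (2.59-fold, exact adjusted p = 8.7e-07). Chromosome 18 from 15000001 to 20000000 held 86 and 50 (2.68-fold, exact adjusted p = 8.7e-07), and from 20000001 to 25000000 it held 44 and 12 (5.70-fold, exact adjusted p = 2.0e-07). Chromosome 6 from 40000001 to 45000000 held 71 and 35 (3.16-fold, exact adjusted p = 6.7e-07). Without dense blocks the calls on the AGS windows of chromosomes 8, 10, 11 and 12 named here ended. The chromosome 3 window, which contains a dense HUG1N block, kept 69 and 48 peaks there and fell below the 2-fold limit (1.94-fold, exact adjusted p = 0.00751).

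Of 561 windows tested, 50 were higher in AGS and 52 in HUG1N (two-sided Fisher exact test with Benjamini-Hochberg adjustment, adjusted p under 0.05 and at least 2-fold). Chromosome X carried 14 of the windows higher in AGS, chromosome 5 carried 8 and chromosome 14 carried 7. Of the windows higher in HUG1N, 12 lay on chromosome 3, 7 on chromosome 6, and 6 each on chromosomes 10 and 18. At a score of at least 100 the split was 6 higher in AGS and 36 in HUG1N among 141 windows, with none of the AGS ones on chromosomes 5, 14 or X and 2 of the HUG1N ones on chromosome 5. With windows of 1 Mb it was 9 and 38 among 881, and with windows of 10 Mb 50 and 29 among 298. Without dense blocks the split became 60 higher in AGS and 30 in HUG1N, and 45 and 28 of the original calls were kept. The windows higher in HUG1N then numbered 7 on chromosome 3, 5 on chromosome 6, 4 on chromosome 18 and 1 on chromosome 10. The window of chromosome 12 from 25000001 to 30000000, which held 335 AGS and 44 HUG1N peaks with all peaks (4.90-fold), turned to HUG1N (19 and 39 peaks, 2.77-fold, exact adjusted p = 0.00347). At a score of at least 100 without the blocks, 2 windows of 135 were higher in AGS and 0 in HUG1N.

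**Figure D3:**
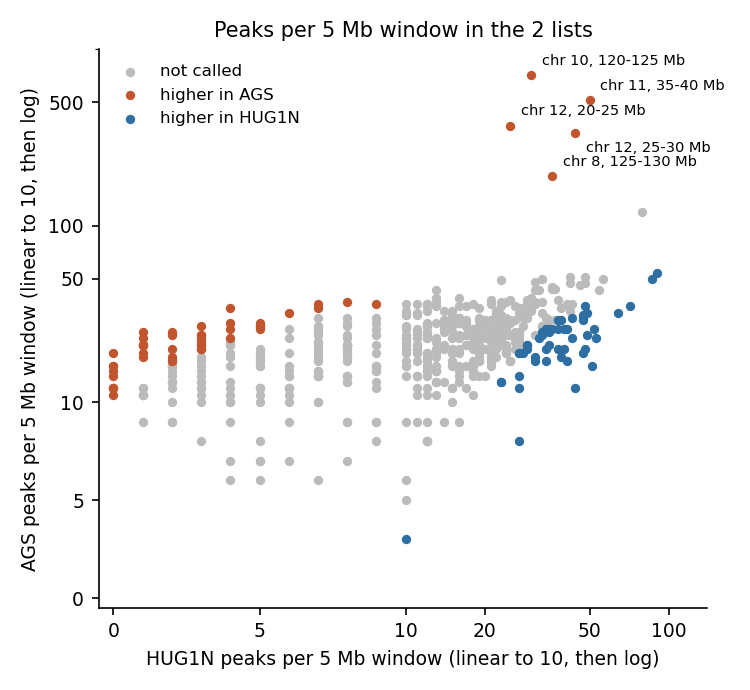
AGS peaks against HUG1N peaks per 5 Mb window, both axes linear to 10 and logarithmic above, 1 point per window, coloured by the Fisher test call. The 5 labelled windows on chromosomes 8, 10, 11 and 12 hold 191 to 713 AGS peaks and 25 to 50 HUG1N peaks.

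Peaks in close succession formed long runs in AGS and short ones in HUG1N. Joining peaks with gaps of up to 10 kb gave 21 clusters of 5 or more peaks in AGS, with 2203 peaks (14.9% of the list), and 10 in HUG1N, with 82 peaks (0.866%). The largest AGS cluster ran on chromosome 12 from 24557706 to 25376585 and held 670 peaks over 24.9% of its length. A chromosome 10 cluster from 122569173 to 123650130 held 520 peaks that covered 89.7% of it, and a second one from 122069327 to 122387864 held 177 peaks over 89.0%. On chromosome 11, 292 peaks covered 80.0% of 34924557 to 35385922, and 244 covered 44.8% of 37935626 to 38157168. The largest HUG1N cluster, 34 peaks on chromosome 16 from 44943280 to 44992425, met 19 AGS peaks. The next ones held 6 peaks each, on chromosome 18 from 17922389 to 17948672, chromosome 20 from 6619632 to 6641325 and chromosome 8 from 26521859 to 26542837. A cluster on chromosome 1 from 158145947 to 158153118 held 5 peaks.

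Dense blocks were then marked by a rule set after these clusters were seen. They are runs of 100 kb windows with 5 or more peaks, in which up to 2 successive windows may hold fewer, and with 20 or more peaks in all. AGS had 6 and HUG1N had 2. The 5 AGS blocks that were not dense in HUG1N, on chromosomes 8, 10, 11 and 12, spanned 4023 kb and held 2083 AGS peaks (14.1%) but 47 HUG1N peaks (0.497%). They took 46.2% of the length covered by AGS peaks and all 100 of the AGS peaks with the highest scores. The chromosome 10 block, from 122023173 to 123650130, held 698 AGS peaks and 11 HUG1N peaks. The chromosome 8 block, from 128314464 to 129074446, held 162 AGS peaks with a median width of 1474 bp, against 195 bp outside all blocks. The block on chromosome 16 was dense in both lists. The other HUG1N block, on chromosome 3 from 170442456 to 170887744, held 21 HUG1N peaks and 6 AGS peaks.

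**Figure D4:**
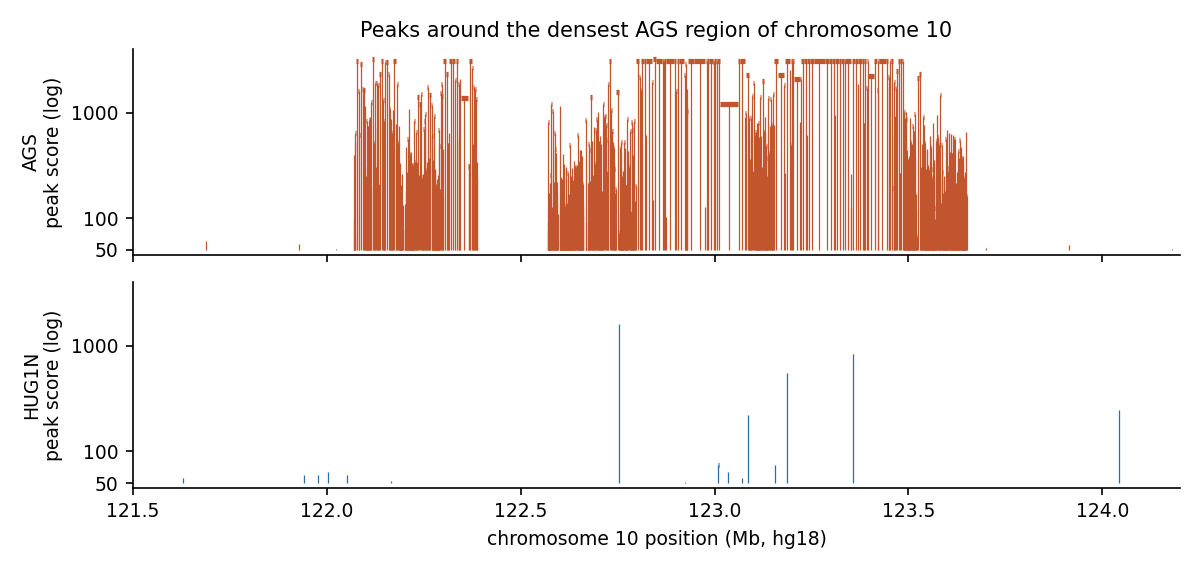
Peaks of AGS (top) and HUG1N (bottom) on chromosome 10 around the block from 122023173 to 123650130 (hg18). Vertical lines rise from the minimum score of 50 to each peak's score (log axis) and horizontal marks give its width; 698 AGS peaks and 11 HUG1N peaks lie in the dense block.

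Many of the strongest individual HUG1N peaks were on chromosome 18, where the GATA6 gene also lies, and several of them had no AGS partner. Of the 10 HUG1N peaks with the highest scores, 5 were on chromosome 18, and of the 20 highest 7 were. Of the 50 highest 8 were (16%), and of the 100 highest 11 (11%). Outside dense blocks, 1 of the 10 highest AGS peaks was on it, from 16769367 to 16774472 (score 1075.30), and it was overlapped in HUG1N. The first HUG1N peak, on chromosome 18 from 20372343 to 20373148, had a score of 2412.95 and was not overlapped in AGS. The peaks at 22294298 to 22295154 (score 2186.33) and 18176511 to 18177257 (score 2126.42) were not overlapped either. Those at 3592836 to 3593411 (2243.56) and 19443336 to 19444017 (1852.30) were. The other 5 of the 10, on chromosomes 1, 10 and 20, were all overlapped in AGS, among them the chromosome 10 peak at 112607934 to 112608458 (2397.61) and the chromosome 20 peak at 29662150 to 29662485 (1754.56). The next HUG1N peaks without a partner were on chromosome 3 from 171531487 to 171532019 (1377.48) and chromosome 6 from 43600157 to 43600695 (1367.23).

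**Figure D5:**
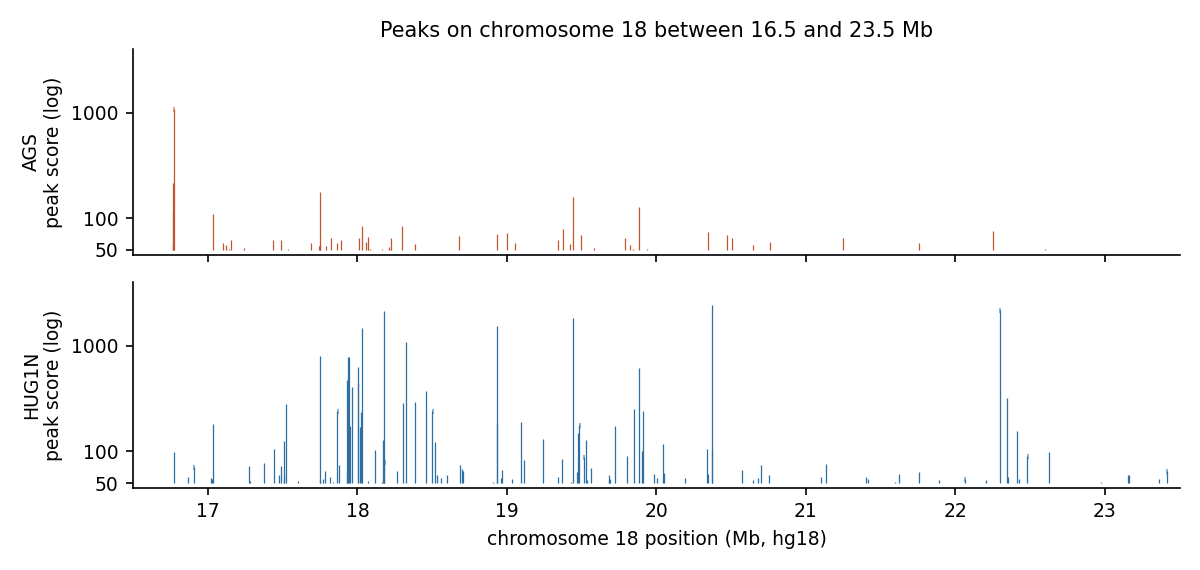
Peaks of AGS (top) and HUG1N (bottom) on chromosome 18 in the middle part of the windows from 15000001 to 25000000 (hg18). The outer ends of these windows are not drawn. Lines rise from a score of 50 to the peak's score on a log axis. The HUG1N peaks with scores of 2412.95, 2186.33 and 2126.42 have no overlapping AGS peak.

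The AGS peaks with scores of 3100 or more all lay in dense blocks, and the 4 of them above 3100 were not overlapped in HUG1N. By score the first was on chromosome 10 from 122115444 to 122120415 (3226.07), and a chromosome 11 peak from 35223750 to 35226782 had 3199.75. An exact score shared by 97 peaks may be a value set by the caller. The 4 peaks above it then need not be the strongest. The other 6 of the 10 AGS peaks named by the rule were among the 97 tied at 3100 and were taken by width. Their lack of a HUG1N partner depends on that order. With the 4 peaks above 3100 ranked first, 0 to 6 of the 10 highest are overlapped, depending on how the tie is broken. Of the 97 tied peaks, 10 were overlapped. Outside the blocks and on the 23 chromosomes compared, the highest AGS peaks without a HUG1N partner were on chromosome 17 from 10321411 to 10322238 (1322.72) and chromosome 1 from 182426337 to 182426803 (741.49).

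The planned comparisons of GATA motifs, other motifs, promoter distance and fixed gene lists were not run, because no hg18 sequence or annotation was used here. For the same reason no gene is placed at any peak.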

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

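The mitochondrial peaks were counted only after the lists had been seen, and no test was planned for them. They lie outside the chromosomes compared above. The AGS list had 9 peaks on the mitochondrial chromosome, covering 7321 bp, with a median score of 393 and a highest score of 2325. The HUG1N list had 0. Reads of the IgG libraries were not analysed here, and no explanation was tested.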

How the results depend on the processing

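Every setting that leaves out dense blocks, and the split into 10 bins, was chosen after the data were seen. No paired analysis was possible because each group had 1 library, and for the same reason no replicate could be left out. The excess of shared peaks over chance kept its direction and passed its test in all settings, from 9.17-fold to 457-fold, and the cause of the changes below was not tested unless stated.

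A score of at least 100 left 2306 AGS and 2869 HUG1N peaks, or 996 and 2830 without the blocks, by construction. The overlapped AGS share was 14.7% at that score, 9.83% with lists of equal size, 13.1% with 5000 peaks each, 7.58% without the blocks and 31.5% with the score and the blocks together. The HUG1N share was 11.5%, 9.46% and 12.8% in the first 3 of these. The top-minus-bottom difference was 22.8 points in AGS without the blocks and 15.7 with 10 bins. In HUG1N it was 26.0 with the AGS list shortened and 39.0 with 10 bins. Shortening the other list changes nothing for AGS, because HUG1N is already the smaller list.

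At a score of at least 100, 4 chromosomes were higher in AGS and 12 in HUG1N, and with the blocks left out too, 3 and 2. Among the chromosomes called with all peaks, the log2 share of HUG1N over AGS turned at that score on chromosomes 4 (0.46), 5 (0.92), 13 (0.39), 14 (0.043) and 15 (0.71). Of these, only chromosome 5 passed the test after turning (1.89-fold higher in HUG1N, exact adjusted p = 0.000211). Chromosomes 8 (-0.75) and 22 (1.91), not called with all peaks, turned and passed the test at that score. With the blocks left out too, chromosomes 4, 5, 13, 14 and 15 were higher in AGS again, and of them chromosomes 4 and 14 passed the test. Among the called chromosomes the log2 share turned with clusters counted once on chromosomes 2 (-0.031), 10 (0.30), 11 (0.25) and 12 (0.28), and without the blocks on the same ones (-0.051, 0.29, 0.26 and 0.30). With score and blocks together it turned, among them, on chromosomes 1 (-0.085), 2 (-0.17), 10 (0.16), 11 (0.84) and 12 (0.20). Other chromosomes, not called with all peaks, also changed sign in these last 3 settings, without passing the test after the change.

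Windows higher in AGS numbered 9 with 1 Mb windows, 6 at a score of at least 100, and 2 with the score and the blocks together. Windows higher in HUG1N numbered 29 with 10 Mb windows, 23 with clusters counted once, 30 without the blocks, and 0 with the score and the blocks together. Windows higher in AGS numbered 50 with 10 Mb windows and 37 with clusters counted once. The share of calls that were higher in AGS was 49.0% with all peaks in 5 Mb windows, 19.15% with 1 Mb windows and 63.3% with 10 Mb windows. It was 61.7% with clusters counted once, 66.7% without the blocks, 14.3% at a score of at least 100 and 100% with the score and the blocks together. The direction of the split thus depended on the setting. Clusters numbered 12 in AGS and 9 in HUG1N without the blocks. With gaps of 5 kb they numbered 27 in AGS and 3 in HUG1N. With gaps of 20 kb they numbered 29 in AGS and 35 in HUG1N, so HUG1N then had more clusters. They held 15.3% of the AGS peaks and 2.56% of the HUG1N peaks at that gap.

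The settings fixed for motifs, promoters and gene lists were not run. Without read counts, the effect of depth on list size cannot be measured.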

Other observations

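All tests in this part were chosen after the patterns, the dense blocks included, had been seen, and those on dense blocks and wide peaks also after the values they measure, while the values for the top of the AGS scores and for chromosomes 18 and X had not yet been computed. A first test of carry-over between libraries, on HUG1N peaks in the 5 AGS blocks that were not dense in HUG1N (at most 8.64% of the AGS number), decided nothing, and the test on wide peaks replaced it.

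Wide peaks were regional in HUG1N too. Of its 91 peaks over 1000 bp, 53 were on chromosome 11 between 27165394 and 46533268, 13 on chromosome 3 and 10 on chromosome 18. The other large group, 11 peaks on chromosome 12 between 24845959 and 25266120, lay inside the AGS block of that chromosome. Among the 10 highest AGS peaks of the chromosomes compared, dense blocks left out, 8 had a HUG1N partner. Of the 4 highest of them, 3 were wide, with 2916 bp on chromosome 6 from 58884427, 4986 bp on chromosome 10 from 41712334 and 5106 bp on chromosome 18 from 16769367.

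The first pattern is the set of 5 dense AGS blocks on chromosomes 8, 10, 11 and 12. In 3 of them, on chromosomes 8, 10 and 11, peaks covered at least 56.87% of the length, with median widths 3.24 to 7.56 times that outside the blocks. The blocks were grouped by covered share after it was seen, so that share cannot test whether separate GATA6 sites were packed closely. The widths show only that peaks in these 3 blocks were not as narrow as elsewhere. The chromosome 12 block had 24.5% covered and a median width 1.32 times that outside, values that closely packed sites would give too. The chromosome 11 block from 37935626 had 44.82% covered and 1.67 times the width. Closely packed sites thus stay open as an explanation. Carry-over of HUG1N DNA left no trace in 6 windows of 1 Mb outside the blocks with 42 wide HUG1N peaks. They held 105 AGS peaks, of which 0 were wide (a share of up to 2.86%, with peaks taken as independent). The windows with wide HUG1N peaks that met AGS blocks were left out, and they held 1 to 83 wide AGS peaks each. Of all wide AGS peaks, 89.1% lay in the 5 blocks. The test therefore cannot decide on carry-over within the blocks. More DNA copies than the control library corrected for may account for the blocks, with a median of 92 times more peaks inside than outside the edges within 200 kb, but the edges were placed by density and IgG reads were not used here, so this stays open for all 5 blocks. The blocks filled the top of the AGS ranking: the highest of 10 score bins was overlapped in 18.03% of peaks against 20.7% in the bin below, and without the blocks in 37.97% against 11.9%.

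The second pattern is the excess of HUG1N peaks on chromosome 18 and their deficit on chromosome X. Dilution of the AGS list by its blocks is argued against as the whole cause for chromosome 18 with all scores, since the fold without them was 2.389 (odds ratio interval 2.00 to 2.97), although the call ended at a score of at least 100 without the blocks. A regional gain of signal on chromosome 18 is a candidate explanation: in 21 shared pairs there the median log2 ratio of HUG1N to AGS score was 1.084 above that of 940 pairs elsewhere (permutation p = 0.00105, adjusted p = 0.0021 over 2 relations), but the bootstrap interval of -0.09 to 1.46 includes 0. For a loss on chromosome X the difference was -0.6696 over 13 pairs (permutation p = 0.1196, interval -1.76 to -0.13), which leaves it open. A difference between the lines in binding or copy number, and a mislabelled library, were not tested.

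The third pattern is that wide HUG1N peaks fell in AGS blocks. All 22 HUG1N peaks in the AGS blocks of chromosomes 11 and 12 were over 1000 bp. Carry-over of AGS DNA into the HUG1N library predicts wide HUG1N peaks also in the AGS blocks of chromosomes 8 and 10. The AGS scores were highest in those blocks. There 0 of 25 HUG1N peaks were wide, which allows a share of up to 12% with peaks taken as independent. The test was chosen after these values were seen, so it cannot decide on carry-over. Other explanations were not tested.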
